A study of Mus musculus with 5 samples.

How the data were processed

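The data were 5 single-cell 3′ RNA libraries of CD4 T cells sorted from digested mouse kidneys (collagenase at 4 mg/ml for 7 min, 70 µm strainer), 2 control and 3 knockout, as grouped by the labels. The deposited files hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 8.0.0 per the file headers. The submitters' processing notes name Cell Ranger 8.0, the mm10 genome and Seurat 5.1.0, whose filters had not been applied to the counts. All 40778 barcodes and 31053 genes were read, and gene positions were taken from GENCODE M21. Nothing in the labels pairs the replicate numbers of the groups.

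Cells with fewer than 500 genes (1906) or with 10% or more mitochondrial UMIs (1133) were removed, which left 38417. Scrublet, run per library, called 1 cell with its own threshold and so removed almost nothing. Removal of the 5% of cells with the highest score in each library was therefore added as an alternative after the data were seen. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and cells were clustered with scanpy 1.11.5 and igraph 0.11.9 (30 principal components, 20 neighbours, Leiden resolution 1) without integration of the libraries. Il1rl1, antigen receptor segments, sex-linked transcripts, mitochondrial, ribosomal, immediate early and heat shock genes were left out of the variable genes. Clusters were named from 27 marker lists, and clusters without a clear match stayed unnamed. "Other T" means all T-lineage clusters except the Treg-like one.

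UMI counts were summed per library and class and tested with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, filterByExpr, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. A further class was tested when every library had at least 50 of its cells. The interaction was fitted with the library as a term. For the ST2 split, control Treg-like cells were thinned to the depth at the 10th percentile of their UMI totals and split by an Il1rl1 UMI, with the library as a term. Gene lists (23 lists, and 14 marker lists of non-T cell types) were tested with camera of limma 3.58.1, with the correlation preset at 0.01 and estimated. Class shares were tested by two-sided exact permutation and by limma on logit shares (0.5 cells added). Other tools were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

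Comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. The rule names, in each direction, up to 12 genes with the smallest p among those that passed and whose libraries do not overlap between groups, filled up to 6 with genes that did not pass. It leaves out antigen receptor segments, gene models without a name, sex-linked transcripts, ribosomal protein genes and members of the non-T marker lists, and it always names a fixed set of Treg and T helper genes. Il1rl1 in the interaction, members of lists, genes called by DESeq2 and the leading genes of clusters were named outside it, after their values were seen. In the further T classes only genes that passed are named. Some genes that the rule names are not reported here.

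The tests were tested on simulated data with the same libraries and 50 genes changed at each of 4 sizes. Of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, edgeR recovered 24%, 76%, 96% and 94% in Treg-like cells (14 false among 159 calls), 30%, 64%, 92% and 86% in other T cells (15 of 151) and 10%, 46%, 74% and 80% over all cells (12 of 117). For the interaction it recovered 40%, 68%, 74% and 74% (13 false of 141) and for the ST2 split 4%, 28%, 46% and 62% (2 of 72). DESeq2 made 5 false calls among 140 in Treg-like cells, 39 among 186 in other T cells and 70 among 195 over all cells. The adjustment is stricter when fewer genes change, so the recovered shares need not hold for the real data. Pcsk1 was more than 4-fold lower in knockout Treg-like cells and did not pass in edgeR, as given below. Of 5 lists moved 1.3-fold among 20 simulated in Treg-like cells, camera found 5 with the preset correlation and 0 with an estimated one, and it called 0 lists that were not moved with either. Genes were drawn independently there, whereas the ribosomal list had an estimated correlation of 0.80 in the ST2 split. The simulation therefore cannot show how often the preset correlation falsely calls lists whose genes vary together.

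The alternatives were DESeq2, RLE factors, no filter on low counts, the replicate number as a block, leaving out each library in turn, lenient and strict cell filters (200 genes and 20%, 1000 genes and 5% mitochondrial UMIs), doublets kept, libraries thinned to the same mean UMIs per retained cell, principal components centred within each library, Leiden resolutions of 0.5 and 2, and Tregs taken by a Foxp3 UMI. Each comparison had only some of them, as planned. Removal of unnamed clusters and of non-T clusters, and the alternatives for the further T classes and for the gene lists of the ST2 split, were added after the data were seen. The Cre and YFP sequences were not analysed here. Exact intervals cover counting error only, and bootstrap intervals come from cells or genes drawn again with replacement. Neither kind covers the spread between libraries.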

Results

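The series asked what regulatory T cells (Tregs) that carry ST2 do in the injured kidney. ST2, the receptor for the alarm cytokine IL-33, is encoded by Il1rl1. Kidneys of 10-week-old mice were taken after ischemia-reperfusion injury of 1 kidney, in which the blood supply is stopped and then restored, and the RNA of CD4 T cells isolated from them by flow sorting was read by single-cell 3′ sequencing. There were 2 control libraries from Il1rl1fl/fl mice, whose Il1rl1 gene carries loxP sites, and 3 knockout libraries from Il1rl1fl/fl Foxp3YFP-Cre mice, in which the Cre recombinase is made under Foxp3, the master transcription factor of Tregs. The Foxp3YFP-Cre allele is present in the knockout group alone, so loss of Il1rl1 and presence of that allele cannot be separated. The labels do not say that each library came from a separate animal. The p-values below for single genes and for class shares measure the spread between these libraries. Those of camera for gene lists instead compare the genes of a list with the other genes. With the preset correlation, camera treats the genes of a list as nearly independent, so its small p-values do not measure the spread between libraries.

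The control libraries held 10146 and 9573 barcodes, and the knockout libraries 4580, 10899 and 5580. Each number was equal to the cell count given in the series' design text. Totals of unique molecular identifiers (UMIs, counted transcripts) were 152275841 and 46383793 in the controls and 41153835, 60421178 and 31104939 in the knockouts. After filtering, 9484 and 9025 control cells and 4241, 10320 and 5346 knockout cells remained. Their median UMIs per cell were 13532.5 and 3786 in the controls and 7546, 4433 and 4115.5 in the knockouts, so that depth differed more within the control group than between the groups.

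Clustering gave 26 clusters, and 33612 of the 38416 cells lay in clusters of the T lineage. A single cluster of 2203 cells was Treg-like, led by Foxp3, Ikzf2 (the Treg factor Helios), Itgae (the integrin CD103), Il2ra (the IL-2 receptor alpha chain) and the inhibitory receptor Ctla4, and 71.5% of its cells had a Foxp3 UMI. Th1-like cells made up 11954 cells in 5 clusters with Cxcr3, Cxcr6, Nkg7, Ccl5 or Il12rb2 among the leading genes. Th17-like cells (1521, led by Il23r, Il1r1 and Ccr6), interferon-like cells (1583, led by Rsad2, Ifit3, Ifit1 and Isg15), naive-like cells (4197, with Ccr7, Igfbp4 and Satb1), proliferating-like cells (2940), CD8-like cells (696), innate-like cells (473) and Th2-like cells (229, with Pparg and Il17rb) were also found. The innate-like cluster was led by Clnk, Ncr1, Klre1, Klrb1c and Klrc2, with Zbtb16 also in its top 10. Most of these are natural killer (NK) cell genes, and 77.6% of its cells had Cd3e, so NK cells and innate-like T cells were not told apart in this cluster, which is counted with the T lineage. The 2 largest proliferating-like clusters were led by histone and DNA replication genes with 0 of the fixed markers among the top 10. The 3 unnamed T clusters held 7816 cells.

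The sort did not remove every other cell type, since 4804 cells lay in macrophage-like, dendritic-like, B-like and proximal tubule-like clusters. These clusters also carried T cell transcripts. Cd3e, a chain of the T cell receptor complex, was found in 80.1% of the cells of the largest macrophage-like cluster and in 67.1% of the B-like cells, against 9.5% of the proximal tubule-like cells. The dendritic-like cluster and 2 of the macrophage-like clusters had median UMIs per cell 2.95, 2.51 and 3.04 times those of the cells' own libraries. Pairs of cells captured together and single cells with free RNA were not told apart in these clusters.

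Il1rl1 was not lower in the knockout Treg-like cells. This gene (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415 on the forward strand of mm10) stood at 115 and 104 CPM (the library-size-scaled UMI counts of edgeR, its cpm unit) in the control Treg-like cells and at 189, 86.4 and 102 CPM in the knockout Treg-like cells, means of 110 ± 7.72 (SD, n = 2) and 126 ± 55.4 (SD, n = 3). The log2 fold change was 0.19 (SE 0.25; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.00), and −0.24 without knockout replicate 1. The deleted exons are not stated in the labels. A 3′ tag outside the deleted part checks nothing, so the level of Il1rl1 could not be used to check the genotype labels, and every direction below rests on them.

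In T cells outside the Treg-like cluster, Il1rl1 was higher in each of the 3 knockout libraries, at 56.3, 34.6 and 24.1 CPM against 9.79 and 8.76 CPM in the controls, a fold of 4.13. The log2 fold change of 2.05 (SE 0.34) had an unadjusted p = 5.40e-04 in edgeR and did not pass the adjustment over 13399 genes (adjusted p = 0.908). DESeq2 called it with the same log2 fold of 2.05 (adjusted p = 9.96e-07), and over all alternatives the adjusted p ran from 5.35e-34 to 1.00. The knockout libraries lay above both controls in the Th1-like (log2 fold 3.12), Th17-like (2.97), naive-like (2.61), interferon-like (2.27), unnamed (2.24) and proliferating-like (1.70) classes, with edgeR adjusted p between 0.208 and 1.00, while in CD8-like cells (0.84) the groups overlapped. The cells of non-T clusters also had more Il1rl1 in the knockout libraries, 37.5 ± 17.8 CPM (SD, n = 3) against 15.6 ± 3.44 (SD, n = 2), a log2 fold of 1.25 (edgeR adjusted p = 0.570).

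Shares of cells with an Il1rl1 UMI were compared after thinning each cell to 2000 UMIs. In Treg-like cells the shares were 15.6% and 15.4% in the controls and 27.6%, 13.2% and 11.3% in the knockouts (unthinned 35.7%, 23.5%, 51.4%, 22.7% and 25.1%). In other T cells they were 1.09% and 1.09% against 9.73%, 5.36% and 2.82% (unthinned 3.22%, 1.74%, 23.0%, 10.3% and 4.47%). B-like cells, taken as a background for this measure, gave 1.06% and 2.21% in the controls and 5.0%, 2.5% and 0% in the knockouts, the last from 38 cells with an upper 95% limit (exact Clopper-Pearson) of 9.25%. The control shares in other T cells were at or near this background. Those of knockout replicates 1, 2 and 3 lay within the upper limits of the B-like share of their own library (12.3%, 13.2% and 9.25%), so the few B-like cells, which also carried T cell transcripts, do not show them above background. Naive-like cells of the same libraries gave 6.9% (95% exact interval 4.14 to 10.7), 0.77% (0.16 to 2.23) and 1.04% (0.34 to 2.42), and in knockout replicate 2 the share of other T cells (4.84 to 5.91) lay above this. Median depths were 13062, 3550, 7234.5, 4188.5 and 3863 UMIs in other T cells and 20361.5, 5413.5, 13385.5, 7746 and 6061 in B-like cells, in the order control replicates 1 and 2 and knockout replicates 1, 2 and 3. Thinning left out 263, 1593, 271, 1413 and 711 other T cells and 4, 97, 19, 117 and 56 Treg-like cells.

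**Figure D1:**
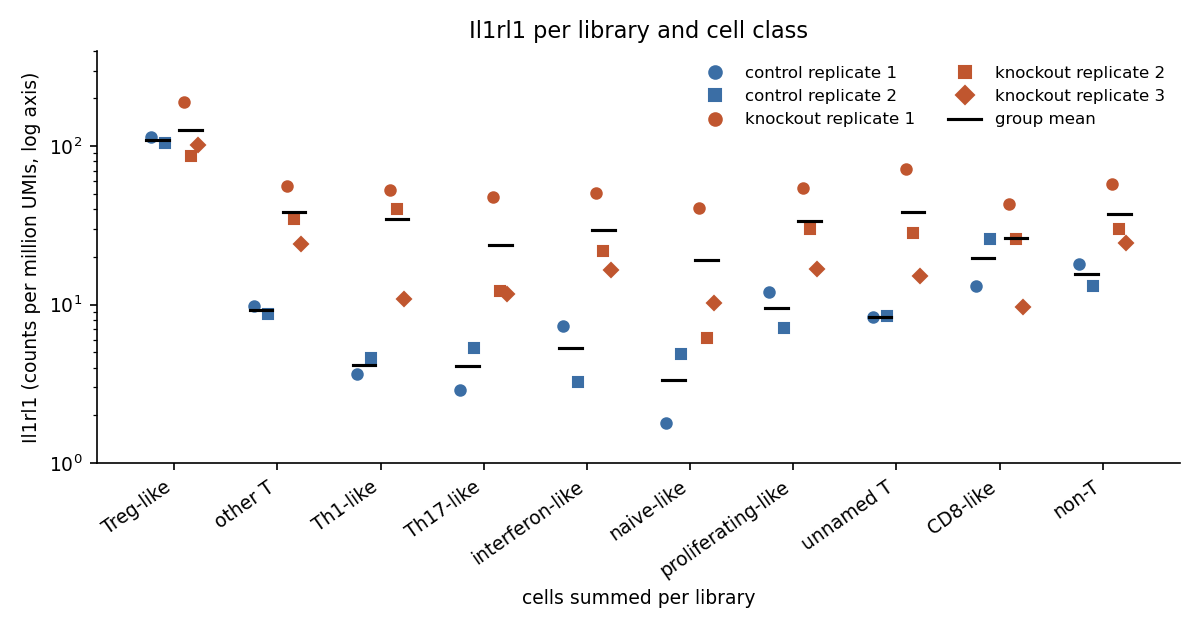
Il1rl1 level in CPM on a log axis for each cell class, with 1 point per library (controls and knockouts in separate colours) and a bar at each group mean. Treg-like cells lie near 110 CPM in the controls and 126 CPM in the knockouts, while other T cells lie at 9.28 CPM in the controls and 38.4 CPM in the knockouts.

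The Treg-like share of T-lineage cells was 5.74% ± 0.274 (SD, n = 2) in the controls and 7.00% ± 1.03 (SD, n = 3) in the knockouts. The 3 knockout values (6.67%, 8.15% and 6.18%) lay above both control values (5.93% and 5.55%). The two-sided exact permutation p = 0.2 is the smallest that the 10 arrangements of 2 against 3 libraries can give, so no share could reach 0.05 by this test. When Tregs were taken instead as T-lineage cells with a Foxp3 UMI, the direction turned, to 7.56% in the controls and 7.06% in the knockouts. That share was not thinned, so it depends on depth, which was highest in control replicate 1. It also depends on the level of Foxp3, which was lower in knockout Treg-like cells, as given below. Whether either turned the direction was not tested.

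Naive-like cells took 18.2% ± 9.25 (SD, n = 2) of T-lineage cells in the controls and 8.17% ± 3.68 (SD, n = 3) in the knockouts (exact permutation p = 0.4; limma on logit shares p = 0.0623, adjusted p = 0.623). The limma adjusted p was 0.393 without control replicate 1 and 0.305 without knockout replicate 1. Th1-like cells took 30.6% ± 6.18 and 37.1% ± 10.3, with 48.0% in knockout replicate 2. That library supplied 85.8% and 96.6% of the cells of 2 Th1-like clusters, both with the macrophage growth factor Csf1 among their leading genes, whereas 63.4% of another Th1-like cluster came from control replicate 2, which also supplied 79.3% of a naive-like cluster. Th17-like cells took 3.22% ± 1.43 and 7.40% ± 8.27, with 16.9% in knockout replicate 1, and proliferating-like cells 7.65% ± 0.0474 and 10.1% ± 5.20. Th2-like cells took 0.499% ± 0.00141 and 0.915% ± 0.586, CD8-like cells 2.42% and 1.63%, innate-like cells 1.92% and 0.995%, interferon-like cells 4.13% and 5.25%, and unnamed T cells 25.7% and 21.5%. All 10 classes had adjusted exact permutation p-values of 0.667 or 0.80 and limma adjusted p-values of 0.623 or 0.679. Among the non-T clusters, proximal tubule-like cells were 0.358% ± 0.0891 of all retained control cells and 0.729% ± 0.173 of knockout cells, dendritic-like cells 1.25% and 0.507%, B-like cells 1.85% and 1.13%, and macrophage-like cells 8.92% and 10.4%. The sort and the digestion set which cells were present, so these shares describe the sorted suspension.

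**Figure D2:**
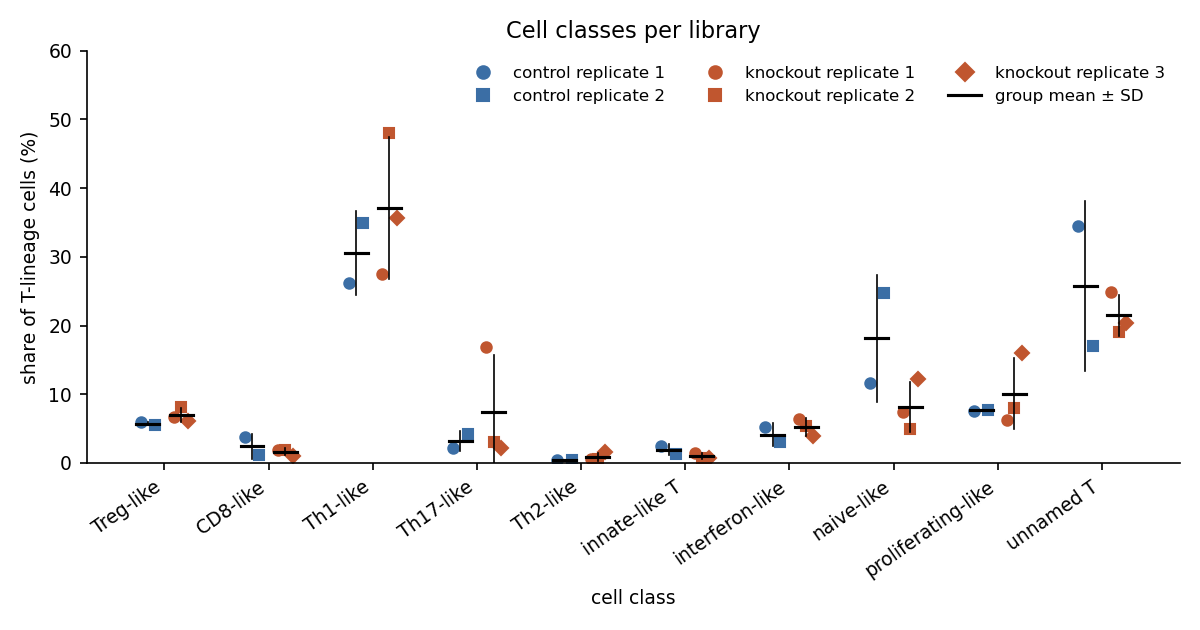
Share of T-lineage cells (%) in each named class, with 1 point per library (controls and knockouts in separate colours, marker shape for the replicate number) and bars for the group mean ± SD. The 3 knockout libraries lie above both controls in the Treg-like class, by 1.26 percentage points on average, and knockout replicate 2 stands at 48.0% in the Th1-like class.

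Within Treg-like cells, the comparison asked what the loss of Il1rl1 changed in the cells where Cre acts. The knockout Treg-like cells had more P2rx7, an ATP-gated ion channel of T cells (log2 fold 0.74, SE 0.12; 126 ± 13.2 against 209 ± 5.48 CPM), Tnfsf8, the ligand of CD30 (1.04), Fhit, a dinucleoside hydrolase (1.07), the Ig-like receptor gene Lilr4b (1.40), the keratin Krt83 (1.31) and the Rap1 regulator Rap1gap2 (1.01). They had less Pcsk1, a proprotein convertase (−2.19, SE 0.30; 30.4 ± 7.85 against 6.73 ± 2.45 CPM), Ahsa1, a co-chaperone of HSP90 (−0.85), Npnt, the matrix protein nephronectin (−1.68), Nav2 (−0.62), the recombination gene Rad51b (−1.08) and Ier5l (−2.43). The libraries of the groups did not overlap for these 12 genes, but 0 of 10081 genes passed in edgeR, where the smallest adjusted p was 0.0912 (Pcsk1). An unadjusted p under 0.05 was reached by 503 genes (229 higher, 274 lower), and DESeq2 called 14 (11 higher, 3 lower), among them P2rx7, Fhit, Tnfsf8, Lilr4b, Rap1gap2, Pcsk1, Nav2 and Rad51b. Other splits of the same libraries gave 0 to 24 DESeq2 calls, with 15 when control replicate 1 and knockout replicate 2 were set apart and 24 when knockout replicates 2 and 3 were, where edgeR called 7. Groups did not overlap in 17.9% of genes, where chance gives 20%. Leaving out control replicate 1, control replicate 2 or knockout replicate 1 gave 5, 5 and 13 calls in edgeR. Lilr4b lies beside its paralogue Lilrb4a on chromosome 10, and how reads of the pair were shared out was not tested.

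Foxp3 itself was lower in knockout Treg-like cells, at 258 ± 24.7 CPM (SD, n = 3) against 370 ± 15.3 (SD, n = 2), without overlap. Its log2 fold of −0.52 (SE 0.12) had an unadjusted p = 8.54e-04 in edgeR and an adjusted p = 0.297. The Foxp3YFP-Cre allele lies in the Foxp3 gene of the knockouts alone. Whether that allele changes the count of 3′ tags of Foxp3 was not tested. The other genes given here from the set fixed for naming also did not pass. Log2 folds were 0.92 (SE 0.61) for Areg, the growth factor amphiregulin, 0.25 for Gata3, 0.84 (SE 0.65) for Il10, −0.03 for Il2ra, −0.03 for Ctla4, −0.24 for Ikzf2, −0.65 for Klrg1 (146.9 against 91.9 CPM) and 0.50 for Tnf. Ifng, the Th1 cytokine, had a log2 fold of 1.39 with 42.6 CPM in knockout replicate 2 (0.41 without that library), and Tbx21, the Th1 factor T-bet, 0.76 (40.3 ± 3.66 against 67.5 ± 20.8 CPM). Leaving out each library in turn gave 0.27 to 4.26 for Areg and −0.21 to 1.92 for Il10. Il17a was below the count filter.

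The Th1 programme was the gene list that set the groups of Treg-like cells furthest apart. Of its 21 measured genes, 20 were higher in knockout Treg-like cells, with a median log2 fold of 0.50. Nkg7, a protein of cytotoxic granules, stood at 102 ± 0.761 against 186 ± 37.2 CPM (log2 fold 0.88), Il12rb2, a chain of the IL-12 receptor, at 8.61 against 36.7 CPM (2.01), Il18r1, the IL-18 receptor, at 244 against 438 CPM (0.84), and Stat4, which signals from the IL-12 receptor, at 376 against 512 CPM (0.44). Over all genes 0 members passed in edgeR, while 11 passed when adjusted over the list alone. The camera test of limma gave adjusted p = 1.11e-15 with the correlation preset at 0.01 and adjusted p = 0.366 with an estimated correlation. The preset call held without each library in turn. Il18r1 lies directly downstream of Il1rl1 on chromosome 1, starting at 40465552 on the same strand, and Il18rap, also on this list, follows it. Whether deletion at the Il1rl1 locus itself changes their RNA was not tested.

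Other lists moved less in Treg-like cells. The killer receptor Klrg1 was lower and Nkg7 and Fasl (0.84) higher in the cytotoxicity list, where 12 of 16 genes were positive (camera adjusted p = 0.00127, and adjusted p = 0.366 with an estimated correlation; 3 higher and 1 lower when adjusted over the list alone). T cell receptor signalling genes were positive in 21 of 25 (Cd6 0.33, Plcg1 0.35; camera adjusted p = 4.84e-04, and 0.530 as adjusted p with an estimated correlation), type II interferon genes in 24 of 27 (Gbp4 0.36, Socs1 0.39; camera adjusted p = 4.84e-04, and adjusted p = 0.597 with an estimated correlation) and inflammatory cytokines in 12 of 18 (Tnfsf8, Ccl3 2.56, camera adjusted p = 0.00264, and adjusted p = 0.366 with an estimated correlation). Lower lists were the cell cycle genes (1 of 29 positive, Cenpf −1.09, Mki67 −0.42; camera adjusted p = 1.99e-05, and adjusted p = 0.597 with an estimated correlation), ribosomal proteins (5 of 77 positive, median −0.11; camera adjusted p = 4.20e-08, and adjusted p = 0.583 with an estimated correlation) and the immediate early and heat shock genes (10 of 31 positive, Jun −0.86, Hsph1 −1.11, against Dusp2 0.76; camera adjusted p = 4.84e-04, and adjusted p = 0.597 with an estimated correlation). The preset calls of the cytotoxicity, type II interferon and inflammatory lists were lost without control replicate 1 (adjusted p = 0.161, 0.318 and 0.558). Those of the cytotoxicity, cell cycle and immediate early lists were lost without control replicate 2 (0.0508, 0.426 and 0.288), and those of the type II interferon and immediate early lists without knockout replicate 2 (0.519 and 0.318). Marker lists of B cells (1 of 4 positive, adjusted p = 0.0313), NK cells (3 of 3, 0.0432) and macrophages (5 of 9, 0.0432) were also called by camera in these cells, with adjusted p = 0.583, 0.530 and 0.656 with an estimated correlation. All 3 were lost without control replicate 1 (camera adjusted p = 0.558), where the macrophage list turned lower.

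The lists nearest to the study's question did not move as sets in Treg-like cells. Treg identity genes were positive in 11 of 25 (camera adjusted p = 0.585), with Itgae (−0.65) and Foxp3 lower when adjusted over the list alone. The tissue-Treg and repair list was positive in 13 of 28 (camera adjusted p = 0.275); adjusted over the list alone, 2 genes were higher, among them Il18r1, and 4 lower, among them Itgae, Dgat2 (−1.29) and Penk, the enkephalin precursor (−1.20). IL-33 and ST2 signalling genes were positive in 12 of 19 (0.241) and Th2 genes in 7 of 11 (0.107), where Plac8 (1.60), Epas1 (1.15) and Il17rb (1.01) were higher when adjusted over the list alone. The Th17 list was positive in 5 of 15 (0.0676), and the lists not named had camera adjusted p from 0.0676 to 0.934.

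**Figure D3:**
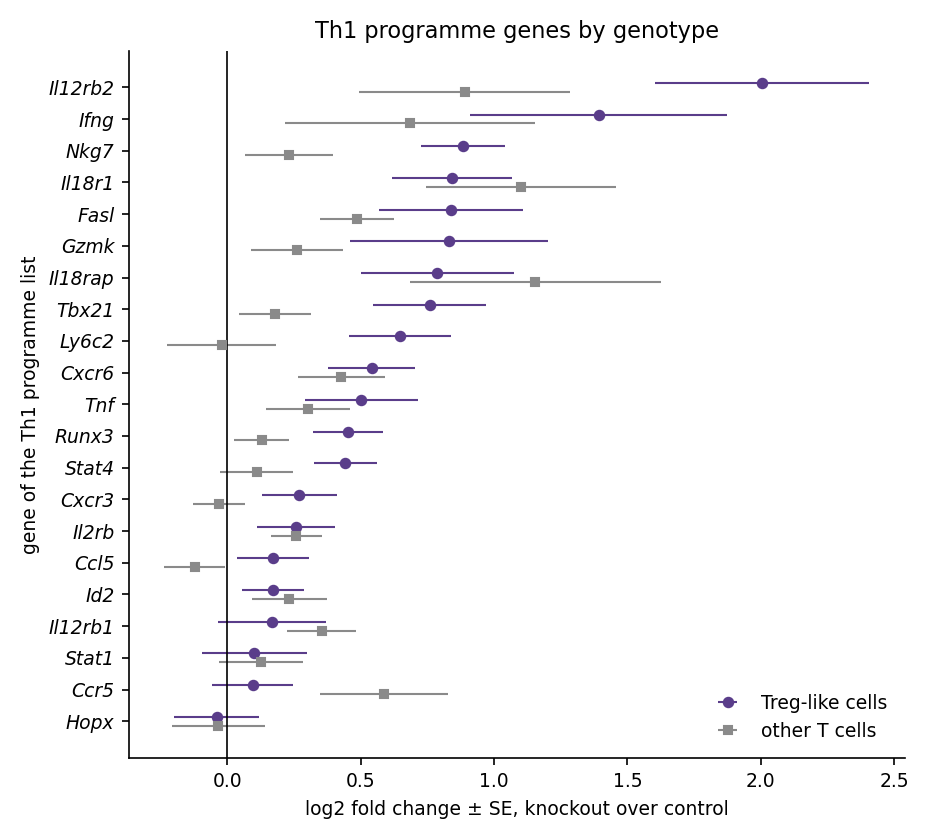
Log2 fold change (knockout against control) with its SE for each of the 21 measured Th1 genes, in Treg-like cells (circles) and in other T cells (squares). In Treg-like cells 20 of 21 points lie to the right of 0, with a median of 0.50.

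T cells outside the Treg-like cluster were compared next. Some of them also had a Foxp3 UMI, such as 19.0% of a naive-like cluster and 13.4% of the CD8-like cells. Action of the Cre in a part of these cells is therefore not excluded. Knockout cells had more Lilr4b (log2 fold 1.52, SE 0.16; 18.4 ± 1.70 against 52.7 ± 8.45 CPM) and its neighbour Lilrb4a (1.20), the autophagy receptor Optn (1.01), AA467197 (1.41), P2rx7 (0.68) and Ddit4, an inhibitor of mTOR signalling (0.88). They had less Ahsa1 (−0.70), Dapl1 (−1.38), a gene of naive T cells, the calcium-binding S100g (−3.39, under 1 CPM in both groups), the kinase Pim2 (−0.69), the epoxide hydrolase Ephx1 (−0.90) and the sialyltransferase St6gal1 (−0.50). The libraries did not overlap for these 12 genes, and 0 of 13399 genes passed in edgeR, where the smallest adjusted p was 0.362 (Lilr4b). An unadjusted p under 0.05 was reached in edgeR by 674 genes (291 higher, 383 lower). DESeq2 called 35 (28 higher, 7 lower), including Il1rl1, Lilr4b, Lilrb4a, Optn, P2rx7 and Pim2. Pim2 lies on chromosome X from 7878262, near Foxp3 (7573644 to 7595245), where the knockouts alone carry the Cre allele. Whether that allele or DNA linked to it changed the RNA of Pim2 was not tested. Groups did not overlap in 17.3% of genes, where chance gives 20%. Leaving out control replicate 2 gave 1 call in edgeR.

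Genes fixed for naming had log2 folds in other T cells of 0.80 (SE 0.21) for Il2ra, 1.57 (SE 0.82) for Areg, 1.13 (SE 0.56) for Klrg1, 1.91 (SE 1.10) for Il17a, 0.69 for Ifng, 0.32 for Ctla4, 0.30 for Tnf, 0.18 for Tbx21, 0.11 for Ikzf2, 0.03 for Gata3, −0.48 for Foxp3 and −0.89 (SE 0.75) for Il10, and none passed in edgeR (adjusted p from 0.959 to 1.00). Single libraries carried several of these values. Knockout replicate 2 stood at 34.4 CPM for Klrg1 and 109 CPM for Ifng, and without it their log2 folds were 0.27 and 0.03. Leaving out each library in turn gave 0.97 to 3.46 for Il17a and 0.77 to 5.13 for Areg. Il10 had 0.774 and 0.392 CPM in the groups, and its log2 fold turned to 0.68 without control replicate 2.

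Naive and ribosomal protein genes were lower in knockout T cells outside the Treg-like cluster. All 20 naive or quiescence genes had negative log2 folds with a median of −0.53, among them Tcf7 (−0.62), a factor of naive and memory T cells, Dapl1 and Tdrp (−1.19). In edgeR 0 passed over all genes and 11 when adjusted over the list alone (camera adjusted p = 2.68e-16, and adjusted p = 0.252 with an estimated correlation). The share of naive-like cells, given above, moved the same way. All 77 ribosomal protein genes were negative (median −0.26, camera adjusted p = 6.90e-25, and adjusted p = 0.230 with an estimated correlation). Both preset calls held without each library in turn.

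Effector lists were higher in these cells. Th1 genes were positive in 18 of 22 (median 0.25, camera adjusted p = 1.32e-06, and adjusted p = 0.339 with an estimated correlation) and cytotoxicity genes in 16 of 19 (camera adjusted p = 2.20e-04, and adjusted p = 0.252 with an estimated correlation), and both held without each library. The tissue-Treg and repair list was positive in 19 of 28, with Il1rl1, Tnfrsf9 (1.08) and Bhlhe40 (0.82) higher when adjusted over the list alone (camera adjusted p = 2.20e-04, and adjusted p = 0.230 with an estimated correlation). Cell cycle genes were positive in 39 of 39 (camera adjusted p = 2.98e-04, and adjusted p = 0.669 with an estimated correlation), but in 11 of 39 without knockout replicate 3 (adjusted p = 0.183; 0.0669 without control replicate 1), the library with 16.0% proliferating-like cells. Smaller camera calls (adjusted p from 0.00129 to 0.0286) were made for the Th2, type II interferon, inflammatory, Treg identity, IL-2 and STAT5, inhibitory receptor and IL-33 lists (higher) and for the type I interferon list (lower), with adjusted p from 0.230 to 0.575 with an estimated correlation. Without control replicate 1 the IL-2 and STAT5 (camera adjusted p = 0.341), Th2 (0.289), inflammatory (0.197), Treg identity (0.162) and type I interferon (0.820) calls were lost, and without control replicate 2 those of the IL-33 (0.206), inhibitory receptor (0.379) and type II interferon (0.0738) lists. In the IL-2 and STAT5 list, Tnfrsf9, Cish (0.81) and Il2ra were higher and Pim2 lower when adjusted over the list alone.

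Markers of other cell types moved with the groups in the same cells. B cell markers were negative in 6 of 6 (Ighm −0.55, Igkc −1.65; camera adjusted p = 1.91e-04, and adjusted p = 0.252 with an estimated correlation), dendritic markers in 7 of 8 (Flt3 −2.18, H2-Ab1 −0.40; camera adjusted p = 2.20e-04, and adjusted p = 0.230 with an estimated correlation), and ILC2 markers positive in 7 of 8 (Il1rl1, Arg1 2.34, Il13 2.52; camera adjusted p = 2.20e-04, and adjusted p = 0.230 with an estimated correlation). The ILC2 call was lost without control replicate 1 (camera adjusted p = 0.0549).

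Over the further T classes, 3 of 69309 tests passed in edgeR, for 2 genes, Lilr4b and Il18r1, which lies next to Il1rl1 as given above. In CD8-like cells Il18r1 rose 2.49-fold (log2 1.32, SE 0.22; 166 ± 15.6 against 395 ± 139 CPM; adjusted p = 0.0237) and Lilr4b rose 3.38-fold (1.76, SE 0.29; adjusted p = 0.0237). In unnamed T cells Lilr4b rose 2.41-fold (1.27, SE 0.13; 21.3 ± 1.33 against 50.6 ± 4.02 CPM; edgeR adjusted p = 0.0299). DESeq2 called Il18r1 in CD8-like cells (adjusted p = 0.00553) and Lilr4b in unnamed T cells (adjusted p = 4.17e-08), and not Lilr4b in CD8-like cells (log2 1.59, adjusted p = 1.00). In CD8-like cells both calls were lost without control replicate 1 (edgeR adjusted p = 0.123 for Il18r1 and 0.720 for Lilr4b), without knockout replicate 1 (0.2 and 0.248) and without knockout replicate 2 (0.340 for both). The call of Lilr4b in unnamed T cells was lost without control replicate 1 (edgeR adjusted p = 0.161) and without knockout replicates 1, 2 and 3 (0.0777, 0.192 and 0.156). Over all alternatives the adjusted p ran from 7.19e-06 to 0.340 for Il18r1, from 1.29e-04 to 1.00 for Lilr4b in CD8-like cells and from 4.17e-08 to 0.192 for Lilr4b in unnamed T cells. In Th1-like, Th17-like, interferon-like, naive-like and proliferating-like cells 0 genes passed in edgeR, with 549, 390, 426, 372 and 404 genes at an unadjusted p under 0.05 and 26, 2, 4, 5 and 16 calls by DESeq2. In CD8-like and unnamed T cells 279 and 397 genes had an unadjusted p under 0.05, and DESeq2 called 1 and 10. The Th1-like sums came mostly from different clusters in different libraries, as given with the shares. The edgeR total of 3 became 39, 176, 8, 0 and 9 without control replicates 1 and 2 and knockout replicates 1, 2 and 3 in turn. The control library alone in the first 2 of these fits is assumed to vary like the knockouts.

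Summed over all cells of a library, the genes with the smallest p that were higher in the knockouts included Cdh6 (log2 fold 7.03, 0.0213 against 2.97 CPM), Dcdc2a (3.25) and Pkhd1 (2.34), genes of kidney tubule epithelium, along with Lilr4b (1.38), Ppl (3.38) and Pdgfd (2.88). Ahsa1 (−0.72), Ephx1 (−0.77), Il6ra (−0.60), Rasgrp4 (−0.66) and Klra6 (−2.77) were lower. The share of proximal tubule-like cells, given above, was also higher in the 3 knockout libraries. In edgeR 0 of 15245 genes passed (smallest adjusted p 0.277), 899 had an unadjusted p under 0.05, and DESeq2 called 123 (97 higher, 26 lower). Groups did not overlap in 18.7% of genes, where chance gives 20%. Camera with a preset correlation called 14 of 35 lists, led by the ribosomal (adjusted p = 3.26e-21) and naive (5.59e-15) lists and by B cell (4.71e-07) and dendritic (1.08e-05) markers, all lower, and 0 with an estimated correlation (adjusted p = 0.554 to 0.564 for these lists). The dendritic call was lost without control replicate 1 (camera adjusted p = 0.11), and the cell cycle list turned from higher to lower without knockout replicate 3 (adjusted p = 0.0346).

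The difference between the genotype effects in Treg-like and other T cells was tested as an interaction, and 22 of 13016 genes passed in edgeR (9 higher, 13 lower), with 866 at an unadjusted p under 0.05. Relative to other T cells, knockout Treg-like cells gained Nkg7 (interaction log2 0.63, SE 0.09, adjusted p = 0.0116; effects of 0.88 and 0.23 in Treg-like and other T cells), Themis, a T cell receptor signalling protein (0.51), the Notch coactivator Maml2 (0.56), the integrin Itgb1 (0.56), Fhit (0.61), Fam102a (0.58), Aff3 (0.72), Nsg2 (0.93) and St8sia1, a ganglioside sialyltransferase (0.76). They lost Il2ra (−0.88, SE 0.12, adjusted p = 0.00598), where the Treg-like effect was −0.03 and the effect in other T cells 0.80, the laminin chain Lamc1 (−1.46, SE 0.16, adjusted p = 0.00138; −0.40 and 1.00), the IL-23 receptor Il23r (−2.07; −0.94 and 1.01), the chemokine Ccl4 (−1.79; −0.66 and 1.02), the syndecan Sdc4 (−1.68; −0.88 and 0.81), Csf1 (−1.95; 0.60 and 2.54), Slc15a3 (−1.64), Dscam (−1.25), Bicd1 (−1.09), Coro2a (−0.74) and Stx11 (−0.69). Il1rl1, named outside the rule because it stands in a marker list, had the smallest p (interaction log2 −1.90, SE 0.16, edgeR adjusted p = 6.1e-05). Some genes of the interaction moved mainly in other T cells. Effects in Treg-like and other T cells were 0.17 and −0.58 for Aff3, 0.25 and −0.64 for Nsg2 and −0.52 and 1.10 for Slc15a3. Others moved mainly in Treg-like cells, such as Themis (0.59 and 0.07) and Maml2 (0.54 and −0.02). The interaction compares log2 folds from unlike starting levels. Mean Il1rl1 went from 110 to 126 CPM in Treg-like cells, from 9.28 to 38.4 in other T cells and from 15.6 to 37.5 in non-T cells. With the spread of the knockout Treg-like values (SD 55.4), a rise of like size in CPM in each class is not excluded.

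The interaction count depended on single libraries. It was 100 without knockout replicate 1 and 2 without knockout replicate 3, and with Tregs defined by a Foxp3 UMI it was 2. Of the 20 genes named by the rule, 20, 1 and 1 passed in these fits, 5 and 9 without control replicates 1 and 2, and 12 without knockout replicate 2. Il1rl1 passed in each alternative run for the interaction (RLE factors, no filter on low counts, Tregs by a Foxp3 UMI, and each library left out), with log2 from −2.01 to −1.69 and edgeR adjusted p from 9.10e-41 to 0.00376. The effect of Csf1 in other T cells came largely from knockout replicate 2, at 51.7 CPM against 8.77 and 7.32 in the other knockout libraries. That of Sdc4 came largely from knockout replicate 1, at 25.3 CPM against 7.17 and 5.77 in the other knockouts and 4.70 and 10.0 in the controls. Il23r, a leading gene of the Th17-like cluster, stood at 46.4, 25.6 and 6.88 CPM against 12.6 and 13.6 in the controls. Its highest value came from knockout replicate 1, the library with 16.9% Th17-like cells.

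**Figure D4:**
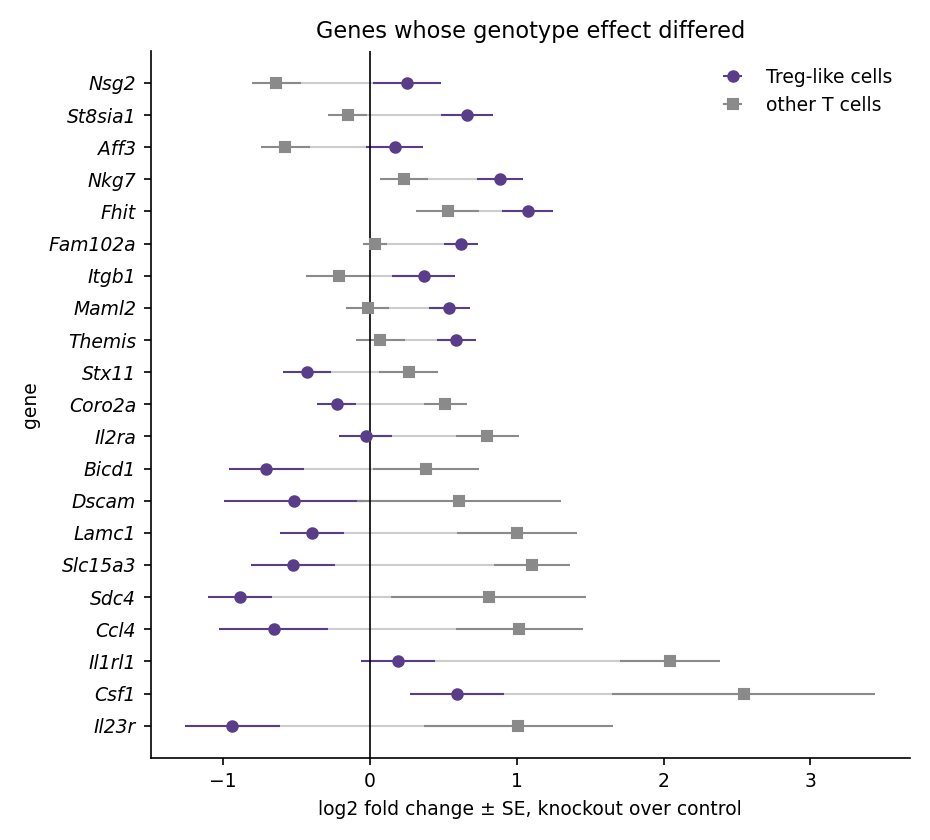
Log2 fold change (knockout against control) with its SE in Treg-like cells and in other T cells for the 20 interaction genes named by the rule and for Il1rl1. Il2ra lies at −0.03 in Treg-like cells and 0.80 in other T cells, and Nkg7 at 0.88 and 0.23.

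The last comparison asked how ST2-positive Tregs differ from ST2-negative ones, within the 2 control libraries, where both kinds of cell come from the same library. Treg-like cells with an Il1rl1 UMI after thinning to 1910 UMIs (69 and 45 cells) had more Frmd5 (log2 1.61, SE 0.24, edgeR adjusted p = 4.63e-08), Nav2 (1.51), the sodium-calcium exchanger Slc24a3 (2.28) and the G protein subunit Gnaq (1.07) than cells with none (426 and 298 cells). They had less Iigp1, an interferon-induced GTPase (−3.11), and Gramd3 (−2.01). The cells were split after thinning. Before it 178 and 102 control Treg-like cells had an Il1rl1 UMI, so the cells with none include some that carried it. In all, 6 of 5797 genes passed in edgeR, 292 had an unadjusted p under 0.05, and DESeq2 called 0. The neuropilin Nrp1 (0.85), Cd200r1 (0.99), the survival factor Bcl2 (−1.59) and the Th1 chemokine receptor Cxcr3 (−1.86) did not pass. Without thinning 18 genes passed, of which Iigp1 and Slc24a3 were shared. Frmd5 (log2 0.73, edgeR adjusted p = 0.445) and Nav2 (0.81, adjusted p = 0.067) did not pass there, and over all alternatives their adjusted p ran from 1.14e-15 to 0.445 and from 1.23e-05 to 0.114. With Tregs defined by a Foxp3 UMI 96 passed, of which 5 were shared. In the 3 knockout libraries 7 of 4508 genes passed, of which Frmd5 and Nav2 (0.96) were shared, while Gramd3 turned to 0.15.

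As groups, type II interferon genes were lower in ST2-positive cells, with 1 of 24 positive (median −0.42; Iigp1, Igtp −1.37, Gbp8 −1.39; camera adjusted p = 3.33e-08, and adjusted p = 0.661 with an estimated correlation). The tissue-Treg and repair list was higher, with 15 of 19 positive (Rora 0.76, Gata3 0.93, Klrg1 0.98, Pparg 2.07; 4 when adjusted over the list alone; camera adjusted p = 7.29e-07, and adjusted p = 0.661 with an estimated correlation), and so was the Th2 list with 6 of 6 (Cd200r1 and Gata3; camera adjusted p = 5.87e-05, and adjusted p = 0.661 with an estimated correlation). Inflammatory cytokines were positive in 0 of 8 and ribosomal proteins in 7 of 77 (camera adjusted p = 8.73e-05 and 8.12e-08, and adjusted p = 0.661 and 0.789 with an estimated correlation). Without thinning the ribosomal list turned higher, with 73 of 77 positive (camera adjusted p = 9.60e-16, and adjusted p = 0.808 with an estimated correlation), and the Th2 (6 of 10 positive) and inflammatory (8 of 17) lists were not called (camera adjusted p = 0.289 and 0.880, and adjusted p = 0.808 and 0.946 with an estimated correlation). The ILC2 markers measured, Rora and Gata3 of the lists above and Il7r (0.41), were positive in 3 of 3 (camera adjusted p = 2.70e-07, and adjusted p = 0.661 with an estimated correlation). In the knockout libraries the tissue-Treg list was positive in 8 of 17 (camera adjusted p = 0.809, and adjusted p = 0.898 with an estimated correlation), the Th2 list in 3 of 6 (0.0803; 0.668), inflammatory cytokines in 3 of 8 (0.288; 0.853) and ribosomal proteins in 40 of 76 (0.887; 0.968), and none of these was called. Type II interferon genes (5 of 23 positive; camera adjusted p = 0.0289, and adjusted p = 0.871 with an estimated correlation) stayed lower there and the ILC2 markers (3 of 3; camera adjusted p = 3.17e-05, and adjusted p = 0.668 with an estimated correlation) higher. Th1 genes were lower in both splits, with 2 of 15 positive in the controls and 5 of 14 in the knockout libraries. Their camera adjusted p was 0.0286 and 0.0289, and 0.661 and 0.668 with an estimated correlation. The type I interferon list was called lower in the controls alone (camera adjusted p = 0.00167, and 0.661 with an estimated correlation). Frmd5 and Nav2, higher in ST2-positive cells, had log2 folds of −1.28 (231 against 94.6 CPM) and −0.62 in knockout against control Treg-like cells. Neither passed in edgeR there, and DESeq2 called Nav2 (adjusted p = 0.0497). Frmd5 lies on chromosome 2 (121545529 to 121807087), near Gm14085 (from 122484941) and AA467197 (from 122636986). DESeq2 called both of these neighbours in other T cells. Whether DNA variants linked to them lowered Frmd5 was not tested.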

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

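The tests of free Il1rl1 RNA, of Treg-like cells mixed into other clusters, of Th2-like cells as the whole source of Il1rl1, of Th1-like cells mixed into Treg-like cells, of linked strain variants and of reads shared between near-identical genes were chosen after the results were seen. The others were written down before, apart from the cut to 19 genes in the test of other T cells mixed into Treg-like cells.

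The genotype effect on the log scale differed between Treg-like and other T cells for 20 genes named by the rule and for Il1rl1, by the interaction test in edgeR. Differences (log2) were positive for Nkg7 (0.63), Maml2 (0.56), Themis (0.51), Fam102a (0.58), Aff3 (0.72), Itgb1 (0.56), Nsg2 (0.93), St8sia1 (0.76) and Fhit (0.61). They were negative for Lamc1 (−1.46), Il2ra (−0.88), Dscam (−1.25), Il23r (−2.07), Coro2a (−0.74), Ccl4 (−1.79), Sdc4 (−1.68), Slc15a3 (−1.64), Stx11 (−0.69), Csf1 (−1.95), Bicd1 (−1.09) and Il1rl1 (−1.90). Of the 20, only 1 still passed with Tregs taken by a Foxp3 UMI, 1 without knockout replicate 3, 5 and 9 without control replicates 1 and 2, and 12 without knockout replicate 2. In data outside the main comparisons, Il1rl1 was higher in the knockout libraries in cells of non-T clusters (log2 1.25).

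Il1rl1 was higher in knockout T cells outside the Treg-like class. Treg-like cells mixed into the other clusters would have raised Foxp3, the single marker tested, by 61.0 CPM, but it differed by −3.37 CPM (SE 2.03), which argues against that source. Th2-like cells, most of which carry Il1rl1, would have needed a rise of 18.3 CPM in their markers, against 2.59 CPM (SE 2.90) seen, which argues against them as the whole source, while a part stays open (12.3 CPM in knockout replicate 3, 6.23 CPM in the higher control). Free Il1rl1 RNA would give Th1-like and naive-like cells of a library the same level. Their ratio was 6.56 (95% bootstrap interval 3.68 to 16.0) in knockout replicate 2, which argues against free RNA as the whole source there.

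In knockout replicates 1 and 3 the ratios were 1.32 (0.973 to 1.87) and 1.04 (0.528 to 3.16), so free RNA stays open in them by this measure. How the interval for knockout replicate 1 was computed was settled after its value was seen. Proximal tubule-like cells of knockout replicates 1, 2 and 3 held 0, 4 and 1 Il1rl1 UMIs (upper limits 3.69, 10.2 and 5.57), where 8.45, 4.55 and 5.61 would come with free RNA at the level of naive-like cells. The count in knockout replicate 1 goes against free RNA at that level, that in knockout replicate 2 leaves free RNA open as a part there, and that in knockout replicate 3 lies at the limit. Free RNA is not excluded by these counts, since it was taken as the same share of UMIs in each class. A biological difference between the genotypes, and the Foxp3YFP-Cre allele itself, stay open and were not tested.

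The Th1 programme was higher in knockout Treg-like cells (median log2 0.50). The 50 genes most specific to other T cells had a median of −0.19 (18 of 50 positive). By the rule written before, this argues against other T cells or their RNA mixed into the Treg-like cluster. The 19 of them at most 2 times as high in proliferating-like as in Th1-like control cells had 0.43 (16 of 19 positive). That cut was not in the written rule, and with it such mixing stays open. The 50 most abundant genes higher in Th1-like cells rose as with 13.1% of added Th1-like RNA (95% bootstrap interval 10.5 to 16.0). This median is near the 11.7% that the Th1 list needs, so Th1-like cells or RNA among the Treg-like cells may be the cause. Of the 50, 41 implied a positive share. Single genes of the Th1 list implied unlike shares, from 4.14% (Ccl5) to 27.2% (Il12rb2), so the medians do not settle it. With Tregs taken by a Foxp3 UMI, the Th1 list had a median log2 of 0.32 (19 of 22 positive). A difference in mean depth is argued against by the median of 0.52 after thinning to the same mean UMIs per retained cell, where Treg-like means lay between 4568 and 5800 UMIs. A Th1-like shift of Tregs that lack Il1rl1 would raise the same genes, and it was not tested apart from mixing or from the Foxp3YFP-Cre allele, which lies in the Foxp3 gene and goes with the genotype.

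DESeq2 called 35 genes in other T cells. Of the 10 splits of the libraries into 2 and 3, 3 gave as many, the real split included, and the highest other gave 133. The splits are too few for a share under 0.05. In the split with 133 calls edgeR called 0 genes, and why DESeq2 called that many was not tested. Linked strain variants stay open. Of the 35 genes, 8 had another called gene nearby, against a median of 4 and an upper limit of 8 in random sets. Nearness to Foxp3, by which Pim2 lies, was not asked by this test. Reads shared between near-identical genes stay open for the 10 genes with a neighbour of like name, among them Il1rl1, Lilr4b, Lilrb4a, Serpina3f and Serpina3g.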

How the results depend on the processing

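The alternatives for the further T classes and for the gene lists of the ST2 split, and the removal of the highest doublet scores, were chosen after the data were seen. Of 1374 values of 179 single genes under alternatives, 1097 kept direction and side of the threshold, 98 lost a call, 177 gained one and 2 changed sign. A further 16 values of genes without a call changed sign within their error and are counted as kept. Of 146 settings of results for a comparison, 106 kept theirs, with counts taken as moved beyond a ratio of 1.5. Of 160 values of interaction genes, 88 kept their call and 72 lost it, with 0 changes of sign. The cause was not tested for any change below unless stated.

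DESeq2 called 123 genes over all cells, 14 in Treg-like cells, 35 in other T cells, 64 in the further T classes and 0 in the ST2 split, where edgeR called 0, 0, 0, 3 and 6. With no filter on low counts edgeR called 6, 146 and 526 genes over all cells, in Treg-like and in other T cells, and 204 in the interaction. In Treg-like cells 1 gene passed with the strict cell filter, with doublets kept, with equal mean UMIs per retained cell and at resolution 2, and 2 with the highest doublet scores removed. With Tregs taken by a Foxp3 UMI the interaction count was 2, the ST2 split gave 96, and the Treg share differed by −0.506 percentage points, against 1.26. Without thinning the ST2 split gave 18, where deeper cells more often have an Il1rl1 UMI.

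The labels do not pair the libraries by number. With the replicate number as a block (a replicate block), edgeR called 93 genes in Treg-like cells, 119 in the further T classes, and 0 over all cells and in other T cells.

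With an estimated correlation, camera called 0 lists over all cells, 0 in Treg-like, 0 in other T cells and 0 in the ST2 split. In the ST2 split it called 10 lists with the preset correlation and 4 in the knockout libraries, and without thinning, where it also called 10, the ribosomal list turned from lower to higher (73 of 77 positive). Il1rl1 in other T cells passed with DESeq2 (log2 2.05, adjusted p = 9.96e-07) and in edgeR with no filter on low counts (2.04), and over all cells with DESeq2 (1.44, adjusted p = 0.00752). The adjusted p ran from 5.35e-34 to 1.00 over the alternatives in other T cells and from 0.00752 to 1.00 over all cells. Il10 in other T cells ran from −1.77 to 0.68 when each library was left out, turning positive without control replicate 2, and Gramd3 in the ST2 split turned to 0.15 in the knockout libraries.

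Leaving out each library in turn gave 0 to 13 genes in Treg-like cells, 0 to 1 in other T cells, 0 to 176 in the further T classes and 2 to 100 in the interaction. It gave 7 to 12 lists in Treg-like cells, 15 to 20 in other T cells and 10 to 18 over all cells. Il1rl1 ran from −0.24 to 0.43 in Treg-like cells, 1.66 to 2.29 in other T cells and 1.01 to 1.68 over all cells. With 2 control libraries, leaving out 1 leaves a lone control that is assumed to vary like the knockouts. At this size the simulated recovery of 1.5-fold changes was 24% in Treg-like cells, so that small changes would mostly be missed. With fewer genes changed than in the simulation, larger changes may be missed too.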

Other observations

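The test of genes higher in ST2-positive control cells was chosen after the result was seen, and the glucocorticoid list was written after the tables were seen. The list chosen in the knockout libraries was tested as written down before.

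Th2-like cells had the highest share of cells with an Il1rl1 UMI at equal depth, 61.0% and 48.7% in the controls and 52.4%, 52.1% and 59.7% in the knockouts. Macrophage-like cells had 2.07% and 2.23% in the controls and 7.84%, 4.2% and 3.58% in the knockouts.

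Genes that mark ST2-positive Treg-like cells may be lost with Il1rl1. The 30 genes with the smallest p among those higher in ST2-positive control cells had a median log2 fold of −0.0237 in knockout against control Treg-like cells (16 of 30 negative), at percentile 17.5 of random lists matched on expression. The 30 genes chosen the same way in the knockout libraries had a median of 0.0232 (13 of 30 negative, percentile 55.4). Neither list was lowered as a set beyond random lists, while its members went both ways and single genes stay open.

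Ddit4, Tsc22d3 and Txnip, targets of the glucocorticoid receptor, stood among the higher genes of several knockout classes, so that glucocorticoid exposure might differ between the groups. The members of a glucocorticoid list not seen before had a median log2 fold of 0.0756 in Treg-like cells (7 of 12 positive, percentile 90.2 of matched random lists) and 0.12 in other T cells (10 of 16 positive, percentile 99.5). The result differs between the classes and leaves the hypothesis open.

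Genes whose libraries did not overlap between the groups in every one of 8 T classes numbered 6 of 7800, with Lilrb4a, Ddit4 and Txnip higher and Ahsa1, St13 and Chd3 lower. The other 9 splits of the libraries gave 4 to 24 such genes, so this number is not unusual. The pattern was first chosen for weighing and was replaced by the genes called by DESeq2 once this was seen.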
